A study of Homo sapiens with 24 samples.

How the data were processed

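Stranded mRNA libraries, made with a TruSeq kit per the labels' protocols, came from MCF10A cells infected with adenovirus. MCF10A is an immortalized, non-tumorigenic human breast epithelial line, grown here in a serum-free mammary epithelial medium with its supplement kit. The conditions were GFP, EGFR, MEK, and EGFR with MEK, with 6 libraries each and 24 in all. Groups and replicate numbers were taken from the labels. The labels do not give the MEK gene or its form, the dose of virus or the time after infection.

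The submitters' processing notes name CASAVA 1.8.2, FastQC, TopHat2 2.0.6, Cufflinks 2.0.2 and the human genome build hg19, without saying how each was used. The annotation and the strand setting are not given in the sources used here. Each library's file holds 22822 genes by symbol, with values deposited by the authors as FPKM, a measure of fragments relative to transcript length and library size. From the values, this FPKM is on a scale set by the upper quartile of each library: the upper quartile of the genes above 0 lay between 341504 and 356127 in every library. The normalization option itself is not stated. The reference annotation at hand is of another build than hg19, so no coordinates are given.

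All values were divided by 1 constant, 14241, which brings them near the usual FPKM range and leaves ratios between libraries as they were. The result is called scaled FPKM. The pseudocount of 1 and the minimum mean of 1 had been chosen before the data were examined for values on the usual FPKM scale, and they were applied to scaled FPKM. Applying them to the deposited values was an alternative added later. FPKM values are not counts, so no count model was used. Depth was read from the low values: for genes seen in only 2 to 4 libraries, the spacing between values gives what 1 fragment is worth in each library, up to a common factor. From 976 such genes the libraries ranged from 15.9% to 100% of the deepest, and the number of genes listed at 0 from 5517 to 7496. A 0 can be a failed estimate. DDR1, an abundant gene, is listed at 0 in MEK replicate 1 and EGFR+MEK replicate 4 only, MICA in EGFR replicate 3, PHF1 in GFP replicate 2 and ZBTB22 in GFP replicate 5. Rows of small RNAs, 1539 in all, of which 383 were tested, made up 10.0 to 22.2% of the library totals and vary more than other genes. They were kept, and left out as an alternative. No 2 libraries of a group were close enough to be the same library deposited again: the SD of their log2 differences was 0.137 or more. On the 500 most variable genes, 24 of 24 libraries lay nearest their own group.

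Genes with a mean of at least 1 scaled FPKM over the 24 libraries were tested, 12239 in all, on log2(value + 1). limma 3.58.1 in R 4.3.3 was fitted to all 4 groups together with an intensity trend, two-sided, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each adjusted p for a gene comes from this fit. The comparisons were each of the 3 other conditions with GFP, the 3 pairs among those conditions, and the interaction, which is the difference between the MEK effect with and without the EGFR virus on the log2 scale. Gene lists were tested with camera, from limma, at a preset correlation between genes of 0.01 and again with an estimated correlation. Camera compares a list with all other genes tested. The 81 list tests against GFP were adjusted together, and so were those of the remaining comparisons. Other calculations and the plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The steps were tested on simulated data for EGFR against GFP with 12239 genes. Of 67 genes changed 1.25-fold 71.6% were recovered, of 67 changed 1.5-fold 97% and of 66 changed 2-fold 100%. There were 14 false calls among 12039 unchanged genes. The simulated noise was independent and normal, with the spread limma estimated and no trend with depth. These figures therefore hold for the fitted model and need not hold for the real libraries.

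The 29 gene lists were written before the data were examined: ERK pathway output, immediate early genes, EGFR family ligands, ERBB receptors and feedback inhibitors, MAPK cascade components, interferon-stimulated genes, NF-kB and inflammatory cytokines, DNA replication and G1/S, mitosis and G2/M, p53 targets, CDK inhibitors, basal mammary keratins and markers, luminal mammary markers, epithelial junction genes, mesenchymal and EMT genes, extracellular proteolysis and invasion, keratinocyte cornification genes, cholesterol biosynthesis, fatty acid synthesis, the unfolded protein and integrated stress response, heat shock proteins, hypoxia and glycolysis, FOXO targets, nucleolar ribosome biogenesis, ribosomal protein genes, mitochondrially encoded genes, and markers of fibroblasts, endothelium and leukocytes. They hold 599 entries, of which 571 were found by symbol and 28 were not analysed here. Lists with at least 4 tested members were tested, 27 in all.

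The genes named in the text were chosen by a rule fixed before the data were examined. EGFR, MAP2K1, MAP2K2 and the members of the ERK pathway output list are always named. For each comparison with GFP the rule allows the 10 largest rises and 10 largest falls past the threshold whose 6 values in the compared groups do not overlap. For the other comparisons it allows the 5 largest of each, by threshold alone for the interaction. From each other list it allows the 2 largest rises and 2 largest falls past the threshold in each comparison with GFP, and for a list with none, its 2 most highly expressed members. Loci without a gene symbol, small RNAs and symbols shared by several entries are passed over, and some genes the rule allows are not reported here.

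The alternatives chosen before the data were examined were a pseudocount of 0.1, no filter on low values, division of each library by its median ratio to the geometric mean over libraries (median-ratio scaling), the replicate number as a block, only the compared groups fitted, each replicate number left out of every group in turn, an estimated correlation for the lists, and 3 GFP libraries used for each comparison in place of all 6. Those added after seeing the data were the settings on the deposited scale, removal of small RNA rows, of the 3 shallowest libraries and of both, log2 relative depth as a covariate for the share of higher calls in EGFR+MEK against GFP, the genes called with both viruses when 3 GFP libraries were used for each comparison, and the comparison of each virus effect between backgrounds. Comparisons that share the GFP libraries were set beside 100 simulations of unchanged groups, with noise drawn independently for each gene and library.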

Results

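Gene expression was measured by stranded mRNA sequencing in MCF10A cells, an immortalized, non-tumorigenic line of human breast epithelium. The cells were infected with adenovirus carrying GFP, EGFR or MEK, or carrying EGFR and MEK together. Each of the 4 conditions had 6 libraries, 24 in all, and the labels do not say which MEK gene was used, whether it was an activated form, the virus dose or the time after infection. The series was made to obtain expression signatures of the EGFR and MEK pathways, so the comparisons below ask what each virus changed relative to GFP, how the viruses differed, and whether their effects added. Values are scaled FPKM, the deposited values divided by 1 constant, and log2 fold changes are on log2(value + 1), which understates the changes of low genes. Each library held 22822 genes, of which 5517 to 7496 were listed at 0, and 12239 genes with a mean of at least 1 were tested. Relative depth, read from the spacing of low values, was 58.6 ± 9.9% of the deepest library in GFP, 57.8 ± 16.2% in EGFR, 59.6 ± 27.6% in MEK and 42.8 ± 21.0% in EGFR+MEK (SD, n = 6 each). The shallowest libraries were EGFR+MEK replicate 5 at 15.9%, MEK replicate 4 at 19.9% and EGFR+MEK replicate 6 at 20.2%. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

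The rows of the introduced genes moved little. EGFR, the receptor tyrosine kinase introduced by the first virus, stood at 73.0 ± 2.88 (SD) in GFP libraries and 83.1 ± 8.91 (SD) in libraries labelled EGFR, where it reached at most 95.5 in any library (log2 fold change 0.18 ± 0.058 (SE), adjusted p = 0.034). It was lower than in GFP in the libraries labelled EGFR+MEK, at 60.7 ± 4.31 (SD), and in those labelled MEK, at 57.5 ± 3.30 (SD). MAP2K1, which encodes MEK1, rose from 38.4 ± 1.19 (SD) in GFP to 42.8 ± 0.992 (SD) in MEK libraries (log2 fold change 0.15 ± 0.036 (SE), adjusted p = 0.0033), and in EGFR+MEK libraries it was 39.6 ± 2.68 (SD), with a log2 fold change of 0.04 that did not pass against GFP (adjusted p = 0.37). That value passed after median-ratio scaling (0.11, adjusted p = 0.0172) and, in an alternative added after seeing the data, without the 3 shallowest libraries (0.10, adjusted p = 0.0186), over a range of 0.0172 to 0.764 among the alternatives. MAP2K2, which encodes MEK2, was 248 ± 11.2 (SD) in GFP, 247 ± 20.3 (SD) in MEK and 227 ± 16.3 (SD) in EGFR+MEK libraries, and fell in EGFR libraries to 210 ± 15.4 (SD) (adjusted p = 0.0048). Against MEK libraries, which lack the EGFR virus by label, the EGFR row in EGFR+MEK libraries did not pass (log2 fold change 0.08, adjusted p = 0.45). Its interaction did not pass either (-0.10, adjusted p = 0.52). The EGFR row therefore neither bears out nor rules out the label of the EGFR+MEK libraries. No row shows a large rise of an introduced gene, so groups are named here by their labels. The EGFR rise in EGFR libraries over GFP was lost with only the compared groups fitted (adjusted p = 0.0542). It was also lost when replicate 1 (0.133), 2 (0.0805), 3 (0.0891) or 6 (0.128) was left out of every group. Its adjusted p ranged from 0.0113 to 0.133 among the alternatives.

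**Figure D1:**
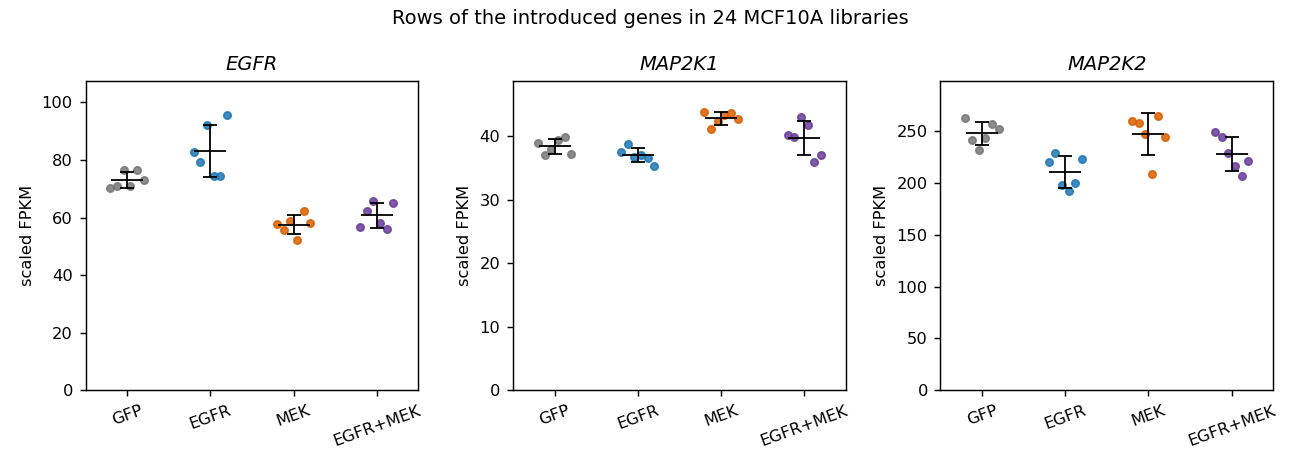
Scaled FPKM of EGFR, MAP2K1 and MAP2K2 (y axes) in each of the 24 libraries by group (x axes), with 6 points per group and bars for the mean ± SD. EGFR averages 73.0 in GFP, 83.1 in EGFR, 57.5 in MEK and 60.7 in EGFR+MEK libraries.

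In libraries labelled EGFR, 30 of 31 genes of DNA replication, 27 of 29 of mitosis and 16 of 27 interferon-stimulated genes rose, and 12 of 24 p53 target genes fell. With an estimated correlation the replication list kept its call (adjusted p = 0.0095), and the mitosis (adjusted p = 0.067), interferon (adjusted p = 0.084) and p53 lists (adjusted p = 0.13) did not. EGR1, an immediate early transcription factor induced by ERK signalling, rose from 23.6 ± 1.93 (SD) to 57.3 ± 5.13 (SD) (log2 fold change 1.246 ± 0.059 (SE), adjusted p = 3.4e-12). DUSP6, a phosphatase that limits ERK activity, rose from 7.87 ± 0.899 (SD) to 14.6 ± 1.01 (SD) (log2 fold change 0.82 ± 0.073 (SE), adjusted p = 6.2e-08). The keratin KRT4 fell from 37.6 ± 5.61 (SD) to 14.8 ± 2.19 (SD) (log2 fold change -1.29 ± 0.12 (SE)), and ID2, an inhibitor of basic helix-loop-helix factors, fell from 44.7 ± 4.75 (SD) to 22.2 ± 0.687 (SD) (log2 fold change -0.97 ± 0.049 (SE)). In all, 2447 of 12239 genes changed at an adjusted p below 0.05, 1247 higher and 1200 lower, and 9 of them changed by at least 2-fold. Small RNA rows aside, 3 were higher and 3 lower by at least 2-fold. Without replicate 1 the count of changed genes was 1456. The median size of the called changes was 1.17-fold, and 11.7% of the genes tested had 6 values in EGFR all above or all below the 6 in GFP, against 0.216% by chance.

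Among the lists, 30 of 31 DNA replication and G1/S genes rose in EGFR libraries, with a median log2 fold change of 0.39. They included CDC45, a subunit of the replicative helicase (log2 fold change 0.54), and POLE2, a subunit of DNA polymerase epsilon (0.50). The list passed camera at adjusted p = 8.6e-30, and at adjusted p = 0.0095 with an estimated correlation. Of 29 mitosis and G2/M genes, 27 rose, among them the spindle checkpoint kinase TTK (0.51) and the phosphatase CDC25C (0.48); the list's adjusted p was 4.5e-23, and adjusted p = 0.067 with an estimated correlation. Interferon-stimulated genes rose in 16 of 27 cases and none fell, led by IFI6 (1.12 ± 0.14 (SE) on log2), IFI27 (1.08) and OAS2 (0.81), with adjusted p = 2.9e-11 for the list and adjusted p = 0.084 with an estimated correlation. Of 24 p53 targets, 12 fell and none rose, among them GDF15 (-0.66) and SESN2 (-0.41), with adjusted p = 1.6e-08 and adjusted p = 0.13 with an estimated correlation. Cholesterol biosynthesis genes rose in 12 of 22 cases, including INSIG1 (0.36), at adjusted p = 4.3e-05 and adjusted p = 0.28 with an estimated correlation. Counts adjusted over the list alone were 30 higher for replication, 28 higher for mitosis, 19 higher and 1 lower for interferon-stimulated genes, 16 lower for p53 targets, and 13 higher and 1 lower for cholesterol biosynthesis.

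The ERK pathway output list, with 14 tested members, was not called in EGFR libraries (adjusted p = 0.49). DUSP6 and PHLDA1 (0.24) rose, while EPHA4 (-0.34), EPHA2 (-0.20) and CCND1 (-0.14), which encodes cyclin D1, fell. DUSP4, DUSP5, SPRY2, SPRY4, SPRED1, SPRED2, ETV4, ETV5 and IER3 did not pass, with log2 fold changes from -0.12 for SPRY2 to 0.21 for ETV4. Immediate early genes rose in 7 of 18 cases, EGR3 (0.83) after EGR1, and 1 fell, with adjusted p = 0.0038 and adjusted p = 0.46 with an estimated correlation. Of the EGFR family ligands, 3 of 6 rose, including HBEGF (0.46) and AREG (0.38), and 1 fell; adjusted p = 0.046, adjusted p = 0.35 with an estimated correlation, 0.068 after median-ratio scaling and 0.066 without the 3 shallowest libraries. Of 18 NF-kB and inflammatory cytokine genes, 5 rose, including the chemokine CCL20 (0.55) and IL1A (0.35), and 1 fell, with adjusted p = 0.023 and adjusted p = 0.47 with an estimated correlation. The metallothioneins MT2A (1.0) and MT1X (0.98) were among the 10 largest rises, as was the interferon-induced IFITM1 (0.71). The hair keratins KRT81 (-1.09) and KRT86 (-1.02), the matrix proteins SPON2 (-0.83) and WISP2 (-0.85) and KRT13 (-0.78) were among the 10 largest falls. Adjusted over the list alone, 2 ERK output genes were higher and 3 lower, 7 immediate early genes higher and 1 lower, 4 ligands higher and 1 lower, and 6 inflammatory genes higher and 1 lower. Keratins and metallothioneins have near-identical copies, so the split of reads among them is uncertain. CCND1 lost its call without replicate 3 (adjusted p = 0.0541, from 0.000551 to 0.0541 over the alternatives) and EPHA2 without replicate 5 (adjusted p = 0.0549, from 0.000446 to 0.0549).

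In libraries labelled MEK, 18 of 23 genes of keratinocyte cornification and 5 of 8 luminal markers rose, and 16 of 27 interferon-stimulated and 16 of 22 cholesterol biosynthesis genes fell. With an estimated correlation the cornification list kept its call (adjusted p = 0.0024), and the luminal (adjusted p = 0.13), interferon (adjusted p = 0.074) and cholesterol lists (adjusted p = 0.081) did not. KRT13, a keratin of stratified non-cornified epithelium, rose from 2.09 ± 0.310 (SD) to 18.8 ± 3.34 (SD) (log2 fold change 2.67 ± 0.12 (SE), adjusted p = 1e-13). KLK7, a protease of the outer epidermis, rose from 3.05 ± 0.457 (SD) to 12.2 ± 1.17 (SD) (log2 fold change 1.71 ± 0.073 (SE)), and the choline transporter-like gene SLC44A2 rose from 11.6 ± 0.456 (SD) to 35.6 ± 2.06 (SD) (log2 fold change 1.53 ± 0.045 (SE)). ISG15, an interferon-induced ubiquitin-like protein, fell from 75.8 ± 6.09 (SD) to 36.5 ± 3.94 (SD) (log2 fold change -1.04 ± 0.081 (SE), adjusted p = 2.3e-09), and EGR1 fell from 23.6 ± 1.93 (SD) to 12.3 ± 0.279 (SD) (log2 fold change -0.88 ± 0.059 (SE)). In all, 2487 of 12239 genes changed, 1260 higher and 1227 lower. They were 1655 higher and 1386 lower after median-ratio scaling. In the alternative without the 3 shallowest libraries, 1700 were higher and 1184 lower. Of these libraries only MEK replicate 4 is in a compared group, but the spread comes from all 4 groups, so each acts on the calls. Without them EGFR against GFP, which holds none of the 3, went from 2447 to 3245 calls. Of the 2487 genes changed in MEK libraries, 45 changed by at least 2-fold, 38 higher and 7 lower. Small RNA rows aside, 38 were higher and 3 lower. Of the genes tested, 11.7% did not overlap between the groups, against 0.216% by chance.

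Of 23 cornification genes, 18 rose and 1 fell in MEK libraries, with a median log2 fold change of 0.88. KRT13 and KLK7 rose most, and the transcription factor KLF4 was the member that fell (-0.34). The list holds KRT13, a keratin of non-cornified epithelium, so the rise of the list is not specific to cornification. The list passed at adjusted p = 1e-20, and at adjusted p = 0.0024 with an estimated correlation. Luminal mammary markers rose in 5 of 8 cases, including ELF3 (0.79) and FOXA1 (0.61), at adjusted p = 0.0001 and adjusted p = 0.13 with an estimated correlation. Basal mammary keratins and markers fell in 8 of 14 cases and rose in 1; the hemidesmosome genes COL17A1 (-0.47) and DST (-0.45) fell most, with adjusted p = 0.00089 and adjusted p = 0.46 with an estimated correlation. Among 23 epithelial junction genes, 9 rose and 5 fell, led by the epithelial transcription factors GRHL1 (1.05) and OVOL1 (0.66); adjusted p = 0.017, and adjusted p = 0.52 with an estimated correlation. Interferon-stimulated genes fell in 16 of 27 cases and none rose, including OASL (-1.16) and IFIT3 (-0.81), with adjusted p = 2e-13 and adjusted p = 0.074 with an estimated correlation. DDX60 (-1.07), which is not in that list, was among the 10 largest falls. Cholesterol biosynthesis genes fell in 16 of 22 cases, including INSIG1 (-0.58) and MVD (-0.56), at adjusted p = 7.5e-11 and adjusted p = 0.081 with an estimated correlation. Fatty acid synthesis genes fell in 5 of 10 cases, including the desaturase SCD (-0.47) and FASN (-0.35), and 1 rose; adjusted p = 0.005, and adjusted p = 0.41 with an estimated correlation. Adjusted over the list alone, 18 cornification genes and 5 luminal markers were higher, and 19 interferon-stimulated, 17 cholesterol, 7 fatty acid and 9 basal genes were lower.

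Of the ERK pathway output list, IER3 (0.52) and PHLDA1 (0.20) rose and DUSP6 (-0.28) and CCND1 (-0.20) fell in MEK libraries, and the list was not called (adjusted p = 0.72). The other 10 members ranged from -0.24 for DUSP5 to 0.12 for SPRY4. Without replicate 6 in any group DUSP6 lost its call (adjusted p = 0.0546, from 0.00506 to 0.0546 over the alternatives). Immediate early genes went both ways (3 higher, 6 lower of 18, adjusted p = 0.21), with FOS higher (0.48) and EGR1 lower. Mitosis genes rose in 12 of 29 cases, including CDK1 (0.35), at adjusted p = 4.3e-06 and adjusted p = 0.37 with an estimated correlation. Replication genes rose in 9 of 31 cases, including the ribonucleotide reductase subunit RRM2 (0.38), and fell in 2, with adjusted p = 0.022 and adjusted p = 0.61 with an estimated correlation. Of 24 p53 targets 1 rose, GDF15 (0.67), and 2 fell (adjusted p = 0.77). Among 16 genes of extracellular proteolysis and invasion, 6 rose, including the hyaluronan synthase HAS3 (0.74), and 3 fell, including the matrix protease MMP7 (-0.72); adjusted p = 0.0078, and adjusted p = 0.47 with an estimated correlation. Adjusted over the list alone, 2 ERK output genes were higher and 3 lower, 12 mitosis genes higher, 11 replication genes higher and 2 lower, 11 junction genes higher and 5 lower, and 7 proteolysis genes higher and 3 lower. Of 4 leukocyte markers 3 also rose, CD14 (0.73) among them (adjusted p = 0.0036, and adjusted p = 0.074 with an estimated correlation). The other large rises included S100P (2.14), which was low in GFP libraries at 1.03 ± 0.665 (SD). With the settings on the deposited scale, an alternative added later, its log2 fold change was 5.01 (adjusted p = 0.0411). KRT4 (1.69), the sterol sulfotransferase SULT2B1 (1.65), KRT81 (1.49), KRT86 (1.42), the retinoic acid binding protein CRABP2 (1.46) and PROM2 (1.45) were also among the large rises.

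**Figure D2:**
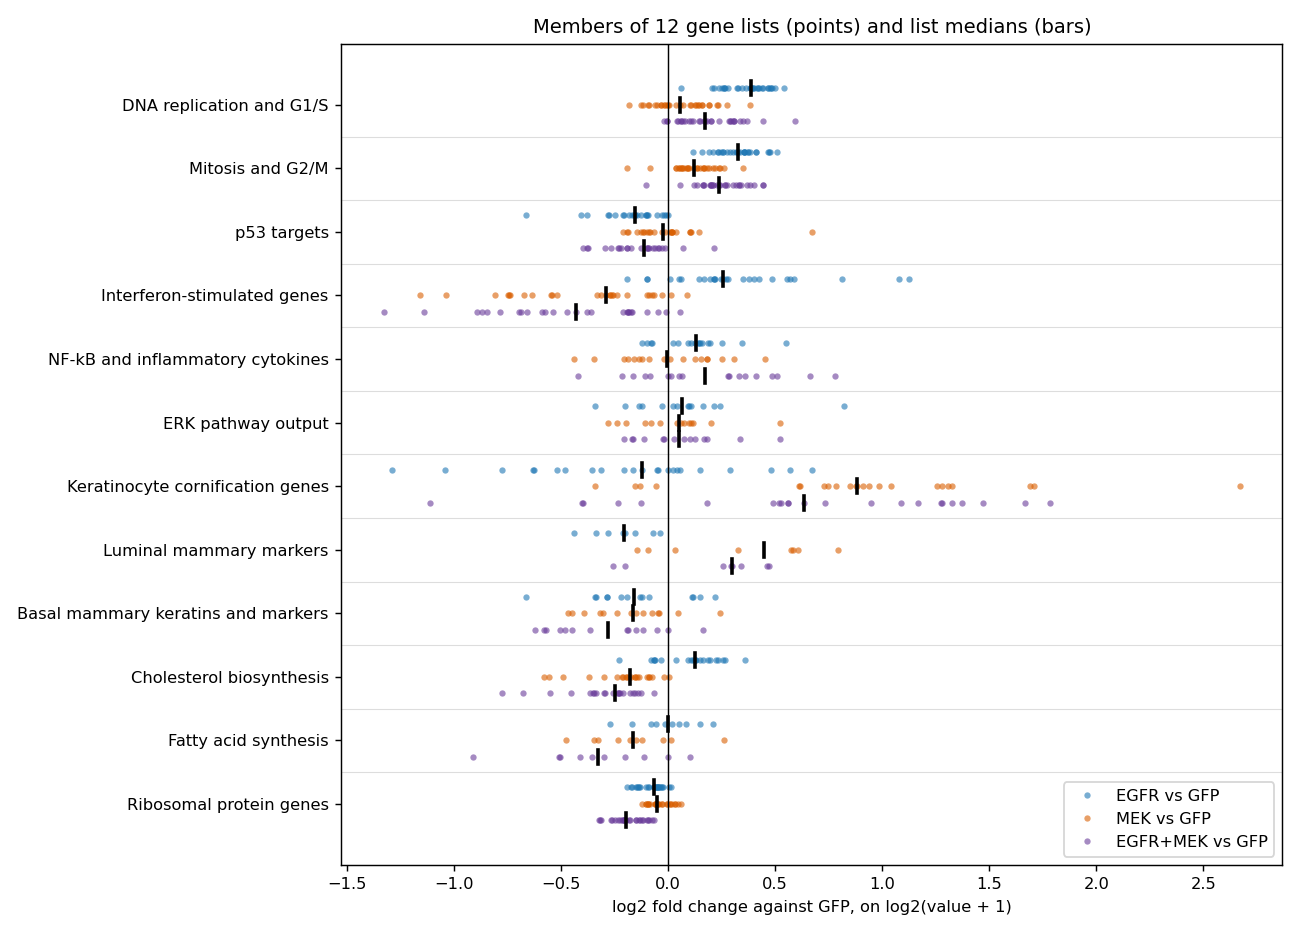
Log2 fold changes against GFP (x axis) of the tested members of 12 gene lists (y axis), 1 point per gene and colour per comparison, with black bars at list medians. Interferon-stimulated genes have medians of 0.26 in EGFR, -0.29 in MEK and -0.43 in EGFR+MEK libraries, and cornification genes -0.12, 0.88 and 0.64.

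In libraries labelled EGFR+MEK, 18 of 23 cornification, 19 of 31 replication, 24 of 29 mitosis and 9 of 18 inflammatory genes rose, and 21 of 27 interferon-stimulated, 20 of 22 cholesterol and 8 of 10 fatty acid genes fell. With an estimated correlation the cornification list kept its call (adjusted p = 0.0024), and the others did not (adjusted p = 0.074 for replication, mitosis and cholesterol, 0.084 for interferon, 0.13 for inflammatory and 0.2 for fatty acid genes). PI3, the elastase inhibitor elafin, rose from 116 ± 7.96 (SD) to 369 ± 12.8 (SD) (log2 fold change 1.66 ± 0.061 (SE), adjusted p = 9.3e-15). SERPINB3, a protease inhibitor of squamous epithelium, rose from 8.02 ± 0.814 (SD) to 24.1 ± 2.63 (SD) (log2 fold change 1.47 ± 0.075 (SE)), and MMP7 fell from 71.3 ± 3.80 (SD) to 29.4 ± 2.65 (SD) (log2 fold change -1.255 ± 0.067 (SE)). In all, 3679 of 12239 genes changed, 1016 higher and 2663 lower, and 13.0% of the genes tested did not overlap between the groups, against 0.216% by chance. After median-ratio scaling 3824 genes changed, 2082 higher and 1742 lower; that scaling centres the typical gene, which brings the directions close to even. EGFR+MEK libraries were also the shallowest group on average, and without the 3 shallowest libraries, an alternative chosen after seeing the data, 1346 genes were higher and 1825 lower.

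Cornification genes rose in 18 of 23 cases and fell in 2, with a median of 0.64, at adjusted p = 2.2e-20 and adjusted p = 0.0024 with an estimated correlation. KRT13 (1.78), SERPINB4 (1.33), and the cornified envelope precursor IVL (1.28, from 0.841 ± 0.181 (SD)) were among the larger rises in the list, and KLF4 (-0.40) and KRT1 (-1.11) fell. SPINK6 (1.5) and KLK14 (1.33), which are not in the list, were among the 10 largest rises. SERPINB3 and SERPINB4 are near-identical copies, so their split is uncertain. The KRT1 call was lost with most alternatives, the removal of any replicate number included (adjusted p from 0.0553 to 0.109, and from 0.0166 to 0.109 over all alternatives). Interferon-stimulated genes fell in 21 of 27 cases and none rose, led by OASL (-1.33) and ISG15 (-1.14); adjusted p = 3.1e-11, and adjusted p = 0.084 with an estimated correlation. DDX60 (-0.94), outside the list, was among the 10 largest falls. Cholesterol biosynthesis genes fell in 20 of 22 cases, including INSIG1 (-0.78) and MVD (-0.68), with adjusted p = 3.4e-12 and adjusted p = 0.074 with an estimated correlation. Fatty acid synthesis genes fell in 8 of 10 cases, including SCD (-0.91) and the regulator SREBF1 (-0.51), with adjusted p = 9.7e-05 and adjusted p = 0.2 with an estimated correlation. Replication genes rose in 19 of 31 cases, including RRM2 (0.59) and GINS3 (0.44), and mitosis genes in 24 of 29, including MYBL2 (0.44) and CENPA (0.44). Their adjusted p-values were 5.7e-15 and 1e-20, and each had adjusted p = 0.074 with an estimated correlation. Adjusted over the list alone, 18 cornification, 19 replication and 25 mitosis genes were higher, and 22 interferon-stimulated, 21 cholesterol and 8 fatty acid genes were lower.

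Inflammatory cytokine genes rose in 9 of 18 cases in EGFR+MEK libraries, led by IL1B (0.78) and CCL20 (0.66), and 2 fell; adjusted p = 9.5e-06, and adjusted p = 0.13 with an estimated correlation. EGFR family ligands rose in 3 of 6 cases, including HBEGF (0.85) and EREG (0.57), with adjusted p = 0.0063 and adjusted p = 0.15 with an estimated correlation. In the ERK pathway output list, IER3 (0.52) and PHLDA1 (0.34) rose and CCND1 (-0.16) and EPHA4 (-0.17) fell, and the list as a whole reached adjusted p = 0.043, upward relative to the other genes, with adjusted p = 0.48 with an estimated correlation, adjusted p = 0.061 after median-ratio scaling and adjusted p = 0.052 without the 3 shallowest libraries. The CCND1 fall was -0.096 after median-ratio scaling and -0.11 without the 3 shallowest libraries, past the threshold in both. The EPHA4 call was lost after median-ratio scaling (adjusted p = 0.122) and without replicate 1, 2, 4, 5 or 6, over a range of 0.0158 to 0.122 among the alternatives. DUSP6 (0.12) did not pass as deposited (adjusted p = 0.21) but passed after that scaling (adjusted p = 0.0438) and without replicate 5 (0.0392), over a range of 0.0392 to 0.525. The other 9 members ranged from -0.20 for DUSP5 to 0.18 for ETV4. EGR1 was 21.9 ± 1.89 (SD), not past the threshold against GFP (log2 fold change -0.10, adjusted p = 0.2). Of 14 basal markers 11 fell, including KRT16 (-0.62) and DST (-0.58), and 1 rose, with adjusted p = 0.00084 and adjusted p = 0.46 with an estimated correlation. Luminal markers rose in 5 of 8 cases, including KRT7 (0.47) and FOXA1 (0.46), and 1 fell; adjusted p = 0.00037, and adjusted p = 0.15 with an estimated correlation. P53 targets fell in 10 of 24 cases, including BBC3 (-0.40) and XPC (-0.38), and 1 rose, with adjusted p = 0.0039 and adjusted p = 0.46 with an estimated correlation. Ribosomal protein genes fell in 19 of 27 cases, including RPL19 (-0.32) and RPS6 (-0.32), at adjusted p = 8.6e-05 and adjusted p = 0.47 with an estimated correlation, and in 13 cases after median-ratio scaling. Adjusted over the list alone, 9 inflammatory genes were higher and 2 lower, 3 ligands higher, 2 ERK output genes higher and 2 lower, 11 basal and 12 p53 genes lower, 6 luminal genes higher and 20 ribosomal protein genes lower. Of 4 leukocyte markers 2 also rose, CD14 (1.14) among them (adjusted p = 0.017, adjusted p = 0.13 with an estimated correlation, 0.060 after median-ratio scaling and 0.065 without the 3 shallowest libraries).

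**Figure D3:**
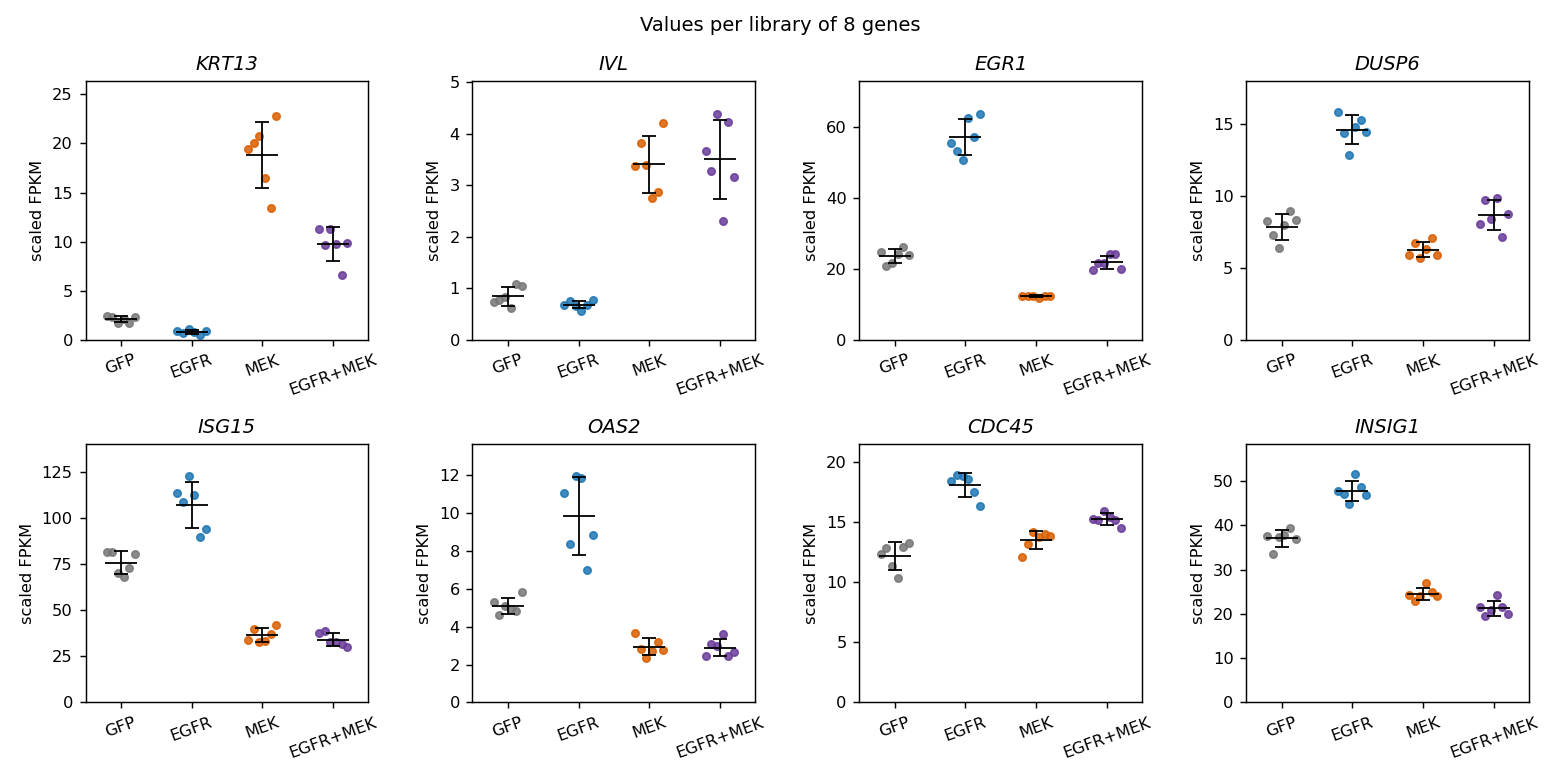
Scaled FPKM (y axes) of 8 genes in each of the 24 libraries by group (x axes), with 6 points per group and bars for the mean ± SD. KRT13 averages 18.8 in MEK and 9.74 in EGFR+MEK libraries against 2.09 in GFP, and EGR1 averages 57.3 in EGFR and 12.3 in MEK libraries against 23.6 in GFP.

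MEK and EGFR libraries differed from each other in 3986 genes, 1903 higher and 2083 lower in MEK. The balance turned to 2332 higher and 2261 lower after median-ratio scaling, and to 2522 higher and 2003 lower without the 3 shallowest libraries. KRT13 (3.45 ± 0.12 (SE) on log2), KRT4 (2.98), KRT81 (2.57) and S100P (2.42) were higher in MEK, and EGR1 (-2.13 ± 0.059 (SE)), DDX60 (-1.54), ISG15 (-1.52), IFI6 (-1.45) and OAS2 (-1.45) were lower. Of 27 interferon-stimulated genes 24 were lower in MEK than in EGFR libraries (adjusted p = 1.6e-20, and adjusted p = 0.023 with an estimated correlation), and of 23 cornification genes 17 were higher (adjusted p = 4.7e-17, and adjusted p = 0.0088 with an estimated correlation). The S100P call was lost with the settings taken on the deposited scale, an alternative added after seeing the data. Its adjusted p was 0.1 there, and from 8.38e-09 to 0.1 over the alternatives, while its log2 fold change was larger, at 3.82.

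When the MEK virus was added to the EGFR virus, by label, cornification genes were higher in 18 of 23 cases (adjusted p = 1.1e-22, and adjusted p = 0.0027 with an estimated correlation). EGFR+MEK libraries differed from EGFR libraries in 3911 genes, 1116 higher and 2795 lower, or 2073 higher and 1895 lower after median-ratio scaling. KRT13 (2.56 ± 0.12 (SE) on log2), KRT81 (2.32), KRT86 (2.21) and SPINK6 (2.28) were higher, and ISG15 (-1.63 ± 0.081 (SE)), IFI6 (-1.5), OAS2 (-1.47), DDX60 (-1.41) and EGR1 (-1.35) were lower. Of 27 interferon-stimulated genes 25 were lower (adjusted p = 1.2e-21, and adjusted p = 0.021 with an estimated correlation), and of 22 cholesterol genes 21 were lower (adjusted p = 2.4e-16, and adjusted p = 0.026 with an estimated correlation). The EGFR row itself was lower in EGFR+MEK than in EGFR libraries (log2 fold change -0.44 ± 0.058 (SE), adjusted p = 4.1e-06).

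When the EGFR virus was added to the MEK virus, by label, fewer genes changed, 824, of which 166 were higher and 658 lower, or 515 higher and 393 lower after median-ratio scaling. The metallothioneins MT1G (0.95), MT1X (0.83) and MT2A (0.72), whose reads can be shared, EGR1 (0.78 ± 0.059 (SE) on log2) and the scavenger receptor OLR1 (0.64) were higher in EGFR+MEK than in MEK libraries. LGALS7 (-1.07), KRT4 (-0.96), KRT13 (-0.88), CYP4F12 (-0.77) and the cell cycle inhibitor CDKN1C (-0.95) were lower. Inflammatory cytokine genes were higher in 6 of 18 cases (adjusted p = 2.6e-14, and adjusted p = 0.021 with an estimated correlation) and replication genes in 9 of 31 (adjusted p = 5.5e-21, and adjusted p = 0.026 with an estimated correlation). None of the 27 interferon-stimulated genes passed in limma here, and their median was -0.07; at an unadjusted p under 0.05, 4 did. With only these 2 groups fitted, 243 genes changed, and leaving out 1 replicate number gave 467 (replicate 1), 392 (replicate 2), 509 (replicate 3), 1131 (replicate 4), 429 (replicate 5) and 423 genes (replicate 6).

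For 436 genes the effects of the viruses did not add on the log2 scale, 73 above and 363 below the sum of the separate effects, or 388 above and 274 below after median-ratio scaling. Interferon genes that rose with EGFR alone did not pass between EGFR+MEK and MEK libraries, and the interaction was -1.17 ± 0.19 (SE) for IFI6, -1.03 for IFI27, -0.83 for OAS2 and -0.75 for BST2, a surface protein that tethers viruses. IFI6 averaged 221 ± 49.5 (SD) in EGFR, 79.0 ± 11.4 (SD) in MEK and 77.3 ± 17.0 (SD) in EGFR+MEK libraries. The signalling ligand WNT4 also lay below the sum (-0.77). SPINK6 (0.93), KRT81 (0.83), KRT86 (0.80) and ID2 (0.76), which fell with EGFR alone and rose with MEK alone, lay above it. Of the lists, interferon-stimulated genes had 13 of 27 members below the sum (adjusted p = 3.4e-13, and adjusted p = 0.058 with an estimated correlation), and replication genes 9 of 31 (adjusted p = 5e-13, and adjusted p = 0.077 with an estimated correlation). The count was sensitive to the libraries used, falling to 102 genes without replicate 1, 146 without replicate 2, 197 without replicate 3, 161 without replicate 5 and 231 without replicate 6.

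Across the 12239 genes, which are not independent replicates, the EGFR and MEK responses were compared first. Their log2 fold changes against GFP correlated at r = 0.349, below the 0.496 ± 0.052 (SD) of 100 simulations of unchanged groups that share the GFP libraries, and the covariance was 0.0287 against 0.0267 simulated. With 3 GFP libraries used for each comparison, r averaged 0.00414 over 20 splits, from -0.045 to 0.0565. Without small RNA rows r was -0.000724 with the shared GFP libraries, against 0.502 ± 0.028 (SD) simulated, and the covariance was -2.1e-05 against 0.00307 simulated. Over the 20 splits r then averaged -0.0696, from -0.142 to -0.0243. Genes called in both comparisons, which share the GFP libraries, numbered 211 higher in both (128.4 for independent lists), 178 lower in both (120.3), 185 higher with EGFR and lower with MEK (125) and 225 the other way (123.5). Part of the excess in the same direction may come from the shared libraries. With 3 GFP libraries for each comparison, counts added after seeing the data averaged 85.55 higher in both (50.42 for independent lists), 54.35 lower in both (37.75), 106.1 higher with EGFR and lower with MEK (45.67) and 139.9 the other way (43.2) over the 20 splits. The effect of each virus was also compared between backgrounds that share no library, a comparison added after seeing the data. The MEK effect without and with the EGFR virus correlated at r = 0.347 (simulated 0.00565 ± 0.064), with 628 genes higher in both (114.9 for independent lists), 858 lower in both (280.2), 33 higher and then lower, and 1 lower and then higher. The EGFR effect without and with the MEK virus correlated at r = 0.0983 (simulated 0.00868 ± 0.067), with 119 genes higher in both (16.91), 244 lower in both (64.52), 10 higher and then lower, and 2 lower and then higher. Without small RNA rows, whose values vary most, r was 0.721 for the MEK effect and 0.436 for the EGFR effect. Without the 3 shallowest libraries it was 0.247 and 0.00786, and without both it was 0.712 and 0.421.

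**Figure D4:**
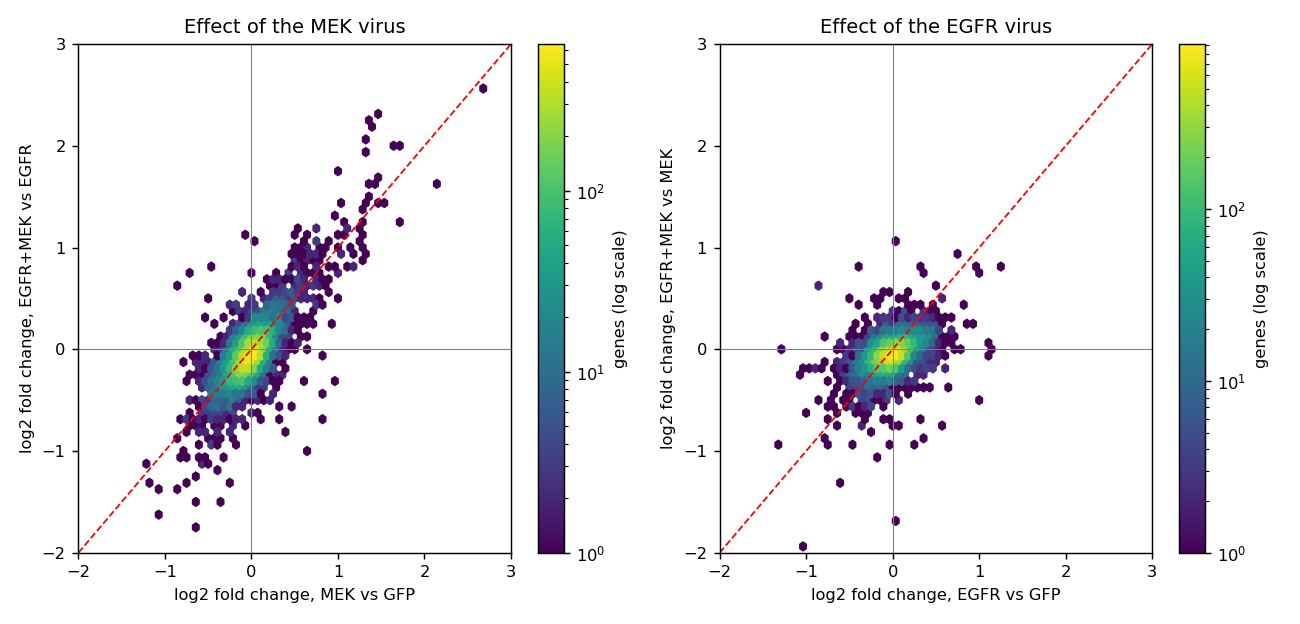
Log2 fold change of each of 11856 genes, small RNA rows left out, for the MEK virus (left) and the EGFR virus (right), without the other virus (x axes) and with it (y axes). Colour gives the number of genes on a log scale, and the dashed line marks equal effects; r across genes is 0.721 on the left and 0.436 on the right.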

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

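The tests of explanations in this part were chosen after the results were seen.

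The first pattern is the EGFR row, which was 1.14 times its GFP mean in libraries labelled EGFR and below GFP in those labelled EGFR+MEK. A missing EGFR virus in the EGFR+MEK libraries, or an exchange of labels with MEK libraries, was set beside the correlation across genes. Between EGFR against GFP and EGFR+MEK against MEK, r was 0.436 without small RNA rows. It was 0.421 with the 3 shallowest libraries left out as well. The bounds from simulated unchanged groups were 0.055 and 0.062. Their noise was drawn independently for each gene and library, so these bounds are too narrow where genes vary together. Over all rows r was 0.0983, within 2 SD of the simulated 0.00868 ± 0.067 (SD), and 0.00786 without the 3 shallowest libraries. Of the 375 genes called in both comparisons, 96.8% went the same way (97.1% without the 3 shallowest libraries), against 49.4% for independent lists. Genes that vary together make that reference uncertain too. Most genes called in both thus went the same way. If the EGFR effect keeps its direction with the MEK virus, exchanged labels of the 2 groups would turn these directions around. The 363 genes that went the same way, against 12 opposite, argue against such an exchange, for the genes called in both. A missing virus cannot be excluded from these values, because genes that vary together could also share a direction. The MEK virus lowering the EGFR row remains a candidate explanation for part of the pattern, because the row fell by 0.44 on the log2 scale in EGFR+MEK against EGFR libraries (adjusted p = 4.1e-06) and by 0.34 in MEK against GFP (adjusted p = 0.00018). Whether reads of an introduced sequence were assigned to the EGFR row cannot be told apart from a low level of it, because values per gene do not show where reads fell, and the ratio of 1.14 does not decide it.

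The second pattern is the direction of the interferon-stimulated genes, higher with EGFR and lower with MEK and EGFR+MEK. Shallow libraries are argued against as the whole cause: without the 3 shallowest, 16 members were lower in EGFR+MEK against 21 with all libraries, and 18 were lower in MEK against 16, while EGFR against GFP holds none of these 3 libraries. GFP libraries that stand apart cannot account for the difference between MEK and EGFR libraries. There 24 of 27 members were lower in MEK, with a median of -0.64 on log2, and no GFP library enters. That comparison follows from those with GFP, so it is no separate test of the pattern. It does not tell whether EGFR raised these genes, MEK lowered them or both, so a shift of the GFP libraries stays open there. The amount of virus per condition cannot be told apart from the genes carried, because the labels give no dose. The 9 of 18 inflammatory genes that rose in EGFR+MEK libraries do not decide it, and a biological effect of each virus stays open as well.

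The third pattern is the excess of falls in EGFR+MEK libraries, where 27.6% of the calls against GFP were higher. Median-ratio scaling centres the typical gene, so its share of 54.4% does not bear on the source. Without the 3 shallowest libraries 42.4% were higher, so falls were still in excess (1346 higher and 1825 lower). With log2 relative depth as a covariate over all 24 libraries 44.4% were higher (1382 higher and 1731 lower), and 42.7% to 48.4% when each library was left out, which is consistent with the authors' scaling at unequal depth as the source of part of the excess. What remains stays open, a biological effect included.

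The size factor of median-ratio scaling followed relative depth over the 24 libraries, with Pearson's r = 0.92 and Spearman's rho = 0.902 (permutation p = 1e-05 each, the smallest that 1e+05 permutations can give, and adjusted p = 2e-05 over 2 relations). Within groups r was 0.941 in GFP, 0.934 in EGFR, 0.95 in MEK and 0.924 in EGFR+MEK, and without the 2 libraries farthest from the median depth it was 0.91 (permutation p = 1e-05). The first principal component, the other relation, gave r = -0.308 (p = 0.15, adjusted p = 0.15) and rho = -0.386 (p = 0.064, adjusted p = 0.064), and r was -0.376 without the same 2 libraries (permutation p = 0.085). Within groups it was -0.268 in GFP, -0.665 in EGFR, -0.869 in MEK and -0.737 in EGFR+MEK, with the same sign in all 4. The second component, with 16.2% of the variance, was not tested against depth. It was 15.5 in EGFR+MEK replicate 5, 8.59 in MEK replicate 4 and 9.83 in EGFR+MEK replicate 6, the shallowest libraries. Deeper libraries also lay high, EGFR+MEK replicate 4 at 9.88 and EGFR replicates 4 and 5 at 9.72 and 12.9.

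A library lay far from the other 5 of its group in 22 of 424 groups of values looked at, against 21.2 by chance, and 12 of the 22 were in MEK replicate 4, a shallow library. The number given is the gap to the nearest other library as a share of the group's range. In MEK replicate 4 it was 0.646 for MAP2K2, 0.714 for EGR1, 0.836 for HBEGF, 0.804 for KRT7, 0.646 for ELF3, 0.702 for HSPA1A, 0.675 for EPHA2, 0.727 for CCND1, 0.813 for COL17A1, 0.683 for SREBF1, 0.649 for RPL19 and 0.691 for XPC, each lower than in the other 5. MEK replicate 5 was high for SPINK6 (0.643). Among GFP libraries, replicate 1 was high for IFI6 (0.714), replicate 2 for CRABP2 (0.663), replicate 5 for TXNIP (0.667) and replicate 6 for KRT1 (0.646, at 16.2 against 1.89 to 6.94). EGFR replicate 1 was high for TTK (0.830). In EGFR+MEK libraries, replicate 5 was low for KRT13 (0.636) and high for CDC25C (0.681), replicate 4 was high for SREBF1 (0.686) and replicate 6 for PI3 (0.673).

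Of 105 genes looked at, 28 had an interaction past the threshold in limma, so that the effect of a virus differed between backgrounds. Over all 12239 genes tested, 436 did. The naming rule picks some genes by their interaction, so the 28 of 105 do not measure how common such genes are. The interactions on the log2 scale were -0.46 for EGR1, -0.56 for EGR3, -0.41 for DUSP6 and -0.29 for CYR61. For interferon-stimulated genes they were -1.17 for IFI6, -1.03 for IFI27, -0.83 for OAS2, -0.75 for BST2, and -0.59 for ISG15, and outside that list -0.56 for IFITM1, -0.34 for DDX60 and -0.30 for TNFSF10. For genes of the cell cycle they were -0.41 for TTK, -0.38 for CDC45, -0.37 for CDC25C and -0.28 for CDK1, and for lipid synthesis -0.55 for INSIG1 and -0.42 for SCD. Above the sum were SPINK6 (0.93), KRT81 (0.83), KRT86 (0.80), ID2 (0.76), WISP2 (0.65), IL1B (0.48) and HAS3 (0.29). Below it were also WNT4 (-0.77), CXCL14 (-0.49) and KLK7 (-0.43).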

How the results depend on the processing

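Alternatives added after seeing the data were the deposited scale, the removal of small RNA rows, of the 3 shallowest libraries and of both, relative depth as a covariate, calls shared with 3 GFP libraries for each comparison, and the comparison between backgrounds. Of 194 values of named genes, 181 passed the threshold, 172 of these passed in the same direction in every alternative run, 9 lost the call in at least 1, and none reversed. The naming rule picks most of these genes by their change past the threshold in these data. Their share of kept calls therefore does not hold for genes at large. Counts of changed genes stayed within 1.5 times, except 662 for the interaction after median-ratio scaling, 243 for EGFR+MEK against MEK with only the compared groups fitted, and some counts with a replicate number left out. These last ran from 1456 to 2364 for EGFR against GFP, 392 to 1131 for EGFR+MEK against MEK and 102 to 483 for the interaction. The log2 fold change of EGFR in EGFR against GFP was 0.18 and not past the threshold with only the compared groups fitted, and 0.14 to 0.22 with a replicate number left out. MAP2K1 in EGFR+MEK against GFP passed at 0.11 after median-ratio scaling and at 0.10 without the 3 shallowest libraries. With a pseudocount of 0.1 the log2 fold changes of some low genes were over 1.5 times as large. In EGFR they were 1.41 for EGR3, -1.29 for KRT13 and -1.36 for WISP2. In MEK they were 1.05 for OVOL1 and 0.91 for FOXA1. In EGFR+MEK they were 1.93 for IVL, 1.06 for OVOL1 and 0.71 for FOXA1, and the interaction of SPINK6 was 1.495. With the settings on the deposited scale these changes were larger still. There S100P reached 5.01 in MEK against GFP (adjusted p = 0.0411) and 3.82 in MEK against EGFR (adjusted p = 0.1). SPON2 was then -1.25 in EGFR and KLK14 2.12 in EGFR+MEK, each also over 1.5 times as large. Of 47 list calls against GFP, 3 held with an estimated correlation, 5 were lost after median-ratio scaling and 7 without the 3 shallowest libraries, each with its value beside the list. The agreement of the EGFR and MEK responses, r = 0.349, was 0.00414 with 3 GFP libraries for each comparison. With all GFP libraries shared it was -0.000724 without small RNA rows (0.502 for simulated unchanged groups) and -0.0202 without these and the 3 shallowest libraries (0.476 simulated). Between backgrounds, r for the MEK effect was 0.247 without the 3 shallowest libraries, 0.721 without small RNA rows and 0.712 without both, and for the EGFR effect 0.00786, 0.436 and 0.421. Except where fewer libraries were used, the cause was not tested. Relative depth ran from 15.9% to 100% of the deepest library, and the shallower a library, the less finely its low values are resolved.

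With the replicate number as a block, the counts in the order EGFR, MEK and EGFR+MEK against GFP were 2829, 2832 and 4216, then 4460 against EGFR and 1177 against MEK for EGFR+MEK, 4420 for MEK against EGFR and 603 for the interaction. MAP2K2 in EGFR+MEK against GFP passed under the block (-0.13, adjusted p = 0.0425), and 1 list call was lost. Libraries share only a number: 23 of 36 same-number pairs correlated above 0.1 (from -0.0398 to 0.331), and 14 of 24 libraries correlated best with their own number.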

Other observations

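The test of the hypothesis in this part was chosen after the result was seen. Cell shape and matrix genes went in several directions. In MEK libraries the intermediate filament gene VIM (-0.47) and the collagen COL6A1 (-0.50) fell, while the actin-binding TAGLN (0.54) and fibronectin FN1 (0.38) rose, with 4 higher and 7 lower of 22 mesenchymal genes (adjusted p = 0.11). In EGFR libraries the list had 5 higher, CTGF (0.60) and CYR61 (0.41) among them, and 3 lower (adjusted p = 0.43), and in EGFR+MEK 4 higher and 8 lower (adjusted p = 0.63). Among basal markers 7 of 14 fell in EGFR libraries, KRT16 (-0.66) among them, and 2 rose (adjusted p = 0.023, and adjusted p = 0.61 with an estimated correlation). Luminal markers fell there in 3 of 8 cases, KRT7 (-0.44) and ELF3 (-0.34) among them (adjusted p = 0.0035, and adjusted p = 0.27 with an estimated correlation). Cornification genes in EGFR libraries had 3 higher, S100A9 (0.67) and S100A8 (0.48) among them, and 6 lower of 23 (adjusted p = 0.034, adjusted p = 0.47 with an estimated correlation and 0.061 without the 3 shallowest libraries). Junction genes had 2 higher and 8 lower in EGFR (adjusted p = 0.029, adjusted p = 0.57 with an estimated correlation and 0.059 with the replicate number as a block), and 7 each way in EGFR+MEK, GRHL1 (1.11) and OVOL1 (0.66) higher (adjusted p = 0.031, adjusted p = 0.57 with an estimated correlation, 0.051 after median-ratio scaling and 0.066 without the 3 shallowest libraries). Proteolysis genes fell in 7 of 16 cases in EGFR, MMP7 (-0.74) among them (adjusted p = 0.0036, and adjusted p = 0.46 with an estimated correlation). In EGFR+MEK 5 rose and 4 fell (adjusted p = 0.023, and adjusted p = 0.55 with an estimated correlation). The S100A8 call in EGFR libraries was lost without replicate 1, 2 or 3 (adjusted p from 0.00952 to 0.0808 over the alternatives). In EGFR libraries 7 basal, 5 luminal, 8 cornification, 9 junction and 8 proteolysis genes were lower adjusted over the list alone, with 4 cornification and 5 junction genes higher. The chemokine CXCL14 fell (-1.15) and SULT2B1 rose (1.54) in EGFR+MEK libraries.

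Unfolded protein response genes rose in 6 of 21 cases in MEK libraries, XBP1 (0.32) and DNAJB9 (0.30) among them (adjusted p = 0.0026, and adjusted p = 0.42 with an estimated correlation). In EGFR+MEK 6 rose and 3 fell (adjusted p = 0.0076, and adjusted p = 0.47 with an estimated correlation), and in EGFR 4 rose and 1 fell (adjusted p = 0.62). Heat shock genes fell in 6 of 12 cases in EGFR, HSPA1A (-0.52), which has a near-identical copy, among them (adjusted p = 0.0063, and adjusted p = 0.47 with an estimated correlation), and in 3 in EGFR+MEK (adjusted p = 0.41). In MEK libraries limma called 0 heat shock genes, and 1 had an unadjusted p under 0.05 (adjusted p = 0.9). FOXO targets had 3, 3 and 2 higher and 4, 7 and 8 lower of 19 in EGFR, MEK and EGFR+MEK (adjusted p = 0.75, 0.21 and 0.12), with TXNIP lower (-0.62) and TNFSF10 higher (0.50) in EGFR+MEK. In the same order, hypoxia and glycolysis genes had 2, 0 and 1 higher and 5, 3 and 12 lower of 23 (adjusted p = 0.11, 0.3 and 0.11), or 6 each way in EGFR+MEK after median-ratio scaling. ERBB receptors and feedback inhibitors had 3, 1 and 3 higher and 0, 1 and 4 lower of 14 (adjusted p = 0.14, 0.77 and 0.33), and MAPK cascade components 2, 1 and 0 higher and 3, 2 and 4 lower of 16 (adjusted p = 0.61, 0.6 and 0.88). Nucleolar genes had 2, 1 and 0 lower and none higher of 26 in limma, with 3, 2 and 5 at an unadjusted p under 0.05 (adjusted p = 0.7, 0.24 and 0.99). Ribosomal protein genes fell in 3 of 27 cases in EGFR (adjusted p = 0.0072, and adjusted p = 0.64 with an estimated correlation) and 1 in MEK (adjusted p = 0.3). Of 5 CDK inhibitors 1 rose and 1, CDKN1C (-0.73), fell in EGFR (adjusted p = 0.87), 2 rose in MEK (adjusted p = 0.0077, and adjusted p = 0.18 with an estimated correlation), and 1 rose and 1 fell in EGFR+MEK (adjusted p = 0.41). Adjusted over the list alone, 8 unfolded protein response genes were higher in MEK, 6 heat shock and 3 ribosomal protein genes lower in EGFR, 2 hypoxia genes higher and 14 lower in EGFR+MEK, and 0 nucleolar genes lower in EGFR. EGFR family ligands in MEK (3 higher, 1 lower, adjusted p = 0.3), inflammatory genes in MEK (3 higher, 4 lower, adjusted p = 0.87), fatty acid genes in EGFR (2 higher, 1 lower, adjusted p = 0.87) and immediate early genes in EGFR+MEK (5 higher, 3 lower, adjusted p = 0.13) were not called.

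Few markers of other cell types were measured. Of 5 fibroblast markers 3 rose in MEK, COL1A1 (0.52) and POSTN (0.43) among them (adjusted p = 0.025, adjusted p = 0.29 with an estimated correlation and 0.055 without the 3 shallowest libraries), 3 in EGFR+MEK, FAP (0.44) and POSTN (0.39) among them (adjusted p = 0.023, adjusted p = 0.29 with an estimated correlation, 0.060 after median-ratio scaling and 0.054 without the 3 shallowest libraries), and 2 fell in EGFR (adjusted p = 0.28). Of 4 leukocyte markers 3 rose in MEK, CD14 (0.73) and CD68 (0.33) among them (adjusted p = 0.0036, and adjusted p = 0.074 with an estimated correlation), 2 in EGFR+MEK, CD14 (1.14) among them (adjusted p = 0.017, adjusted p = 0.13 with an estimated correlation, 0.060 after median-ratio scaling and 0.065 without the 3 shallowest libraries), and 2 fell in EGFR (adjusted p = 0.1). No endothelial marker and no mitochondrially encoded gene was among the genes tested.

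A hypothesis is that the MEK response may be kept and the EGFR response reduced when both viruses are present. Across 11856 genes without small RNA rows, the noise-corrected slope of the MEK effect with the EGFR virus on that without it was 1.04 (jackknife SE 0.085 over 24 libraries), and that of the EGFR effect with the MEK virus on that without it was 0.433 (SE 0.095). The difference was 0.607 (SE 0.074), and 0.571 to 0.63 when each library was left out. Virus dose per condition is not in the labels, so a smaller dose of the EGFR virus in the mixture stays open.

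The libraries of the compared groups were also divided into other groups of the same sizes, in tests planned beforehand. The other libraries kept their labels in the fit, and for the interaction all 24 were divided. That division moves the effects of both viruses into the spread within groups, which lowers the counts of the other splits. The splits for the interaction therefore do not test whether the effects add. Of 100 splits, the real one included, only the real split gave as many changed genes in any comparison, 1 of 100 each. Such counts were thus not reached by the other divisions of these libraries. The labels do not say that replicates came from separate cultures, so chance differences between cultures or infections were not excluded. The real and the highest other counts were 2447 and 431 for EGFR against GFP, 2487 and 663 for MEK against GFP, 3679 and 1612 for EGFR+MEK against GFP, 3911 and 2064 for EGFR+MEK against EGFR, 824 and 135 for EGFR+MEK against MEK, 3986 and 885 for MEK against EGFR, and 436 and 1 for the interaction.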
